A study of Mus musculus with 24 samples.

How the data were processed

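Small RNA was sequenced from 24 samples of mouse origin in 4 materials: exosomes from serum, exosomes released by hepatocytes, the hepatocytes themselves, and liver. Each material had 3 treatments (untreated control, acetaminophen, acetaminophen with granulocyte colony-stimulating factor, G-CSF), and each condition was listed once for the Ion Torrent PGM and once for the Ion Torrent Proton instrument, per the labels. RNA was isolated with a Norgen total RNA kit and libraries were prepared with the Ion Total RNA-Seq Kit v2, per the labels' protocols. The doses were 500 mg/kg acetaminophen and 100 µg/kg G-CSF for serum and liver, and 20 mM acetaminophen and 1 µg/ml G-CSF for hepatocytes and their exosomes, per the labels. The aligner, the annotation release and the genome build are not given in the sources used here, and neither is the number of mice or cultures behind a sample.

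The deposited values are estimated counts (expected counts) per miRNA, not scaled to depth, in a table of 1915 mature miRNAs and a table of 1186 hairpins, per the file headers. Both tables hold 12 columns, 1 per condition, and the column names carry no instrument. The 2 libraries of a condition had therefore been combined by the authors before deposition, per the file headers, and no replicate remained. The rule by which reads matching several miRNAs were divided is not given in the sources used here. All nonzero values were multiples of 1/60 within 0.001, while 67.47% of the mature and 53.52% of the hairpin values were whole within that tolerance. The mature total was whole in 10 of the 12 columns. Of the mature miRNAs, 982 had a count in at least 1 column, as did 1146 of the hairpins.

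Groups follow the treatment characteristic of the labels. For the 4 samples (2 columns) of serum exosomes from acetaminophen-treated mice, the titles give the opposite assignment of G-CSF from that characteristic, and the labels do not settle which is right. The main results use the characteristic, and exchanging both columns was an alternative. All 12 columns were matched to sample titles by name. For those 2 serum columns the names in both tables follow the titles and so go against the characteristic used.

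Comparisons, tests, alternatives, the rule for named miRNAs and 17 lists of miRNAs were fixed before the data were examined. Acetaminophen plus G-CSF against control within a material was not among the planned comparisons. The planned fits of 24 separate libraries with instrument as a block, and everything that needed both instruments apart, could not be carried out on combined columns. The rule used within a material was adopted after the tables had shown no replicates. It called a miRNA different between 2 columns when at least 10 counts were present in 1 of them, the ratio of the scaled counts was at least 2-fold, and the exact conditional (Clopper-Pearson) 95% interval of the ratio excluded equality. Scaling within a material used trimmed mean of M values (TMM) factors from edgeR 4.0.16. Before this, a low-count filter kept miRNAs with at least 10 counts in at least 1 of the 3 columns of the material. In both exosome materials the miRNAs shared by the columns were too few for TMM factors, and the mature column totals were used. A count that rounded to 0 was replaced by a floor of 3 counts and the fold was given as a bound ("at least"). The exact 95% interval reaches closer to equality than such a bound, which takes the other count as known. Shares of a column carry 95% Wilson intervals.

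Comparisons across conditions used edgeR's quasi-likelihood F-test on rounded counts of the 12 columns, with TMM factors, treatments as the replicates of a material and materials as the replicates of a treatment, and Benjamini-Hochberg adjustment within each of the 6 comparisons. Differences between materials in the response to acetaminophen were tested with material by acetaminophen terms, on the 6 columns of hepatocytes and liver and on all 12, a form chosen after seeing the data in place of the planned one on separate libraries. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with the correlation estimated. The median log2 fold of a list with at least 3 measured members was placed among 10000 random lists matched for abundance, which treats members that share reads as separate. Members of the 17 lists found in the table numbered 8 for hepatocyte-enriched, 9 for erythroid, 5 for myeloid, 5 for lymphoid, 2 for endothelial, 9 for mesenchymal and stellate, 6 for biliary and epithelial, 7 for striated muscle, 4 for pancreas, 6 for neural, 9 for the let-7 family, 10 for miR-17-92 and paralogues, 3 for the miR-29 family, 5 for the miR-30 family, 8 for inflammation and injury response, 7 for p53 and hypoxia response and 12 for the imprinted Dlk1-Dio3 cluster, 111 in all with overlaps counted once.

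Named miRNAs were miR-122-5p in every comparison, then up to 10 per direction by size of fold among those called with a mean of at least 50 CPM (counts scaled to the column total), the 10 most abundant of each material, and the most abundant members of the lists. For the comparisons across conditions up to 12 per direction were taken. A miRNA named outside this rule is said to have been chosen after its values were seen.

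The ratio intervals were tested on simulated columns with 200 miRNAs changed. For hepatocytes, acetaminophen against control, the interval covered the true ratio for 97.39% of 115 measured miRNAs, 21 of 31 4-fold and 33 of 39 8-fold changes were called, and 0 unchanged miRNAs were called. For liver, acetaminophen against control, coverage was 95.98% of 174 miRNAs, 36 of 42 4-fold and 35 of 37 8-fold changes were called, and 3 unchanged miRNAs were called. The intervals cover counting error only, so coverage on simulated columns does not show how they hold on the real ones. In the real hepatocyte comparison the hairpin fold lay outside the interval of the mature fold for 26 of 53 called miRNAs. In the real liver comparison it did so for 26 of 78 called miRNAs with a hairpin fold. The fit of 12 columns for acetaminophen against control called 5 of 17 4-fold and 16 of 20 16-fold changes and 2 of 89 unchanged miRNAs among 126 tested at a simulated dispersion of 0.1. At a simulated dispersion of 1 it made 0 calls. The fit of hepatocytes and liver alone called 18 of 22 4-fold and 17 of 17 16-fold changes and 6 of 69 unchanged miRNAs among 108 tested at a dispersion of 0.1, and 0 at a dispersion of 1.

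Hairpin positions were taken by name from the GENCODE M21 annotation of GRCm38, a build chosen here because it was at hand; 1155 of the 1186 hairpins (97.39%) matched and 31 did not. A hairpin was called repeat-like when it shared a 20-mer with at least 20 other annotated genes, which 52 did.

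The alternatives were column totals in place of TMM, DESeq2 1.42.0 with its own size factors, no low-count filter, a stricter filter of a mean of 50 CPM, leaving out miR-122-5p and the next most abundant miRNA before scaling, leaving out each material or each treatment in turn, only the 6 columns of the materials compared, and the exchanged serum labels. Hairpin counts were planned for the comparisons of treatments across materials. Hairpin counts elsewhere and the fit of hepatocytes and liver alone were chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 were used.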

Results

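The 12 deposited columns of mature miRNA counts differed widely in depth. Among serum exosomes, the untreated control column held 6515 counts, the acetaminophen column 436 and the acetaminophen plus G-CSF column 692. Among hepatocyte exosomes the totals were 335, 91 and 47 in the same order. Hepatocytes had 26741, 5330 and 4450 counts, and liver had 49330, 19695 and 43698.7. The hairpin totals were 181243, 460 and 4026 for serum exosomes, 911, 167 and 173 for hepatocyte exosomes, 838624, 179751 and 139361 for hepatocytes, and 1307523, 111316 and 1095868 for liver. Hairpin counts exceeded mature counts 25.08 to 33.72 times in 6 of the 7 columns with more than 1000 mature counts and 5.652 times in the acetaminophen liver column. Acetaminophen is a drug that damages hepatocytes at high doses, and G-CSF is a cytokine that mobilises granulocytes and was given here with it. There are no replicates: each value is that of 1 column made from 2 libraries, and a comparison of 2 columns compares those libraries, not conditions. Intervals, floors and bounds cover counting error only, and the bounds cover it less fully than the intervals.

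miR-122-5p, the miRNA most typical of hepatocytes, was the most abundant in all 3 liver columns, with 11657.2 counts (23.63%) in control, 7902 (40.12%) with acetaminophen and 5543 (12.68%) with G-CSF added. In hepatocytes the leading miRNA was miR-21a-5p in control (5536 counts, 20.7%), miR-122-5p with acetaminophen (920, 17.26%) and miR-30c-5p with G-CSF added (1437, 32.3%). Next by mean share of the 3 columns were miR-191-5p, let-7a-5p, let-7c-5p and miR-451a in liver, and miR-21b, miR-30b-5p, miR-192-5p and miR-215-5p in hepatocytes. A single column carries the rank of miR-451a (5.905% with acetaminophen) and of miR-21b (16.41% in control, under 1% in the others). let-7a-5p and let-7c-5p, and miR-192-5p and miR-215-5p, had nearly equal counts. In control serum exosomes miR-30c-5p alone made up 56.48% (3680 counts) and miR-30b-5p 13.25% (863). In the other serum columns the leading miRNAs were miR-877-3p (18 counts, 4.128%) and miR-466i-3p (43.35 counts, 6.264%). In hepatocyte exosomes they were miR-5129-5p in control (13 counts) and miR-2137 in both treated columns (25 counts, 27.47%, and 6 counts, 12.77%). miR-122-5p had 31 counts (0.4758%) in control serum exosomes and 0 in the other serum columns, which allow shares of up to 0.6881% and 0.4335%, so that a difference was not detectable in mature counts at this depth. Its hairpin had 336.2, 0.5 and 2.75 counts in control, with acetaminophen and with G-CSF added (0.1855%, 0.1086% and 0.0683%). After TMM scaling of the hairpins it was at least 16.4-fold lower with acetaminophen and 114-fold lower with G-CSF added (38.6 to 554), far more than these shares differ. The log2 fold of miR-122-5p with acetaminophen in serum exosomes, a bound, ran from -4.04 (hairpin counts) to 0.53 over the alternatives tried. In hepatocyte exosomes it had 1 count in control (0.2985%), 0 with acetaminophen and 1 with G-CSF added (2.128%), where a count of 0 allows up to 0.8955%, 3.297% and 6.383%.

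Members of the 17 lists, which hold the abundant miRNAs of liver, blood and several other tissues, took 89.26% of the counts (95% Wilson interval 88.48 to 89.98) in control serum exosomes but 1.606% (0.7798 to 3.277) with acetaminophen and 0.7225% (0.309 to 1.68) with G-CSF added. In hepatocyte exosomes the shares were 2.985% (1.629 to 5.407), 3.297% (1.127 to 9.249) and 2.128% (0.3766 to 11.11). In hepatocytes they were 63.37%, 67.56% and 71.91%, and in liver 61.64%, 78.83% and 63.8%. With the 3 treatments as the samples of each material, hepatocyte exosomes against hepatocytes gave a two-sided exact permutation p of 0.1, the smallest that 3 against 3 columns can give. The same exact test gave 0.4 for serum exosomes against liver, 1 for serum against hepatocyte exosomes and 0.9 for hepatocytes against liver.

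**Figure D1:**
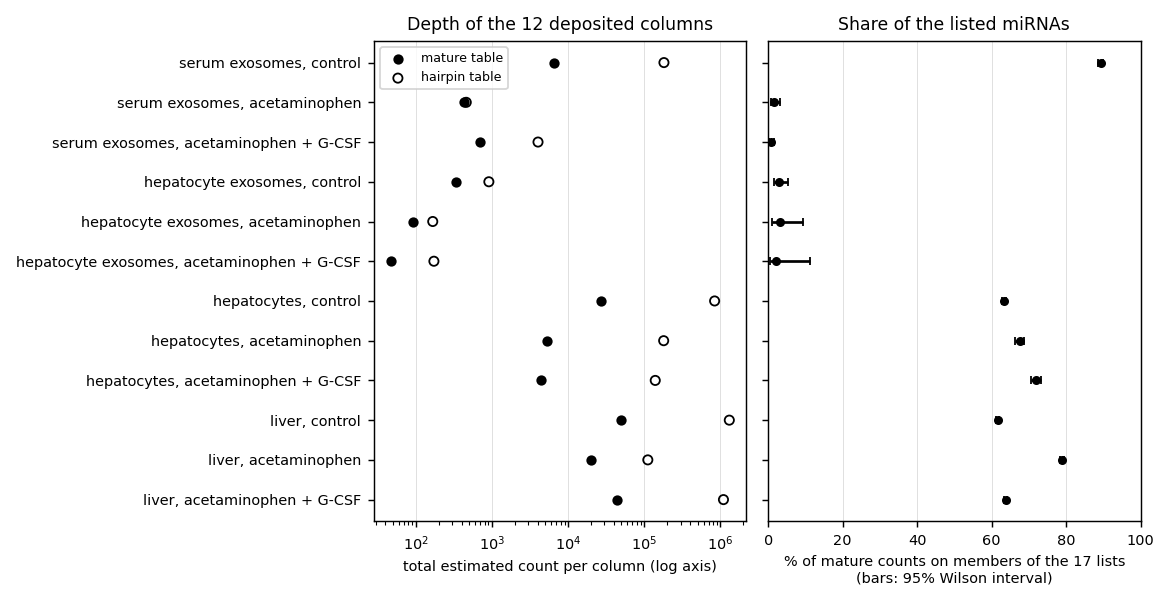
Total estimated counts of each of the 12 columns in the mature and the hairpin table (left, log axis), and the percentage of mature counts on members of the 17 lists with 95% Wilson intervals (right). Listed miRNAs lie at 3.297% or less in the 5 exosome columns with fewer than 1000 mature counts and at 61.64% or more in the other 7.

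Serum exosomes, acetaminophen against control, address which circulating vesicle miRNAs differ after the toxic dose. miR-30c-5p (3680 counts in control, 0 with acetaminophen) was at least 82.1-fold lower in the acetaminophen column, and miR-30b-5p (863 and 0) at least 19.3-fold lower. The exact 95% limits nearest equality were 66.7- and 15.6-fold. The red blood cell miRNAs miR-486a-5p, whose counts equal those of miR-486b-5p (228.7 and 0), miR-16-5p (195.2 and 0) and miR-451a (162 and 0) were at least 5.11-, 4.35- and 3.61-fold lower. miR-195a-5p and miR-380-5p were at least 2.79- and 2.01-fold lower. Entries higher in the acetaminophen column were miR-466i-3p (13.67 against 1 count, 209-fold, 95% interval 31.8 to 8846), miR-7058-3p and miR-877-3p (at least 89.7-fold), miR-669c-3p and miR-706 (at least 74.7-fold), miR-3470b and miR-3472 (at least 69.7-fold), miR-466f-3p (at least 54.8-fold), and miR-6981-5p and miR-7667-5p (at least 49.8-fold). The hairpins of miR-466i, miR-3470b, miR-706 and miR-669c share a 20-mer with 4037, 2382, 727 and 49 other annotated genes, and that of miR-877 with 0. After TMM scaling, the hairpin went the same way for 9 of 10 called miRNAs with a hairpin fold. That of miR-877 had a log2 fold of only 0.42. miR-2137 was 29.9-fold higher (10 against 5 counts), but its hairpin stood at 0.357 times control (0.197 to 0.599). As a share that hairpin was higher too (3.259% against 0.1584%), so its direction depends on the scaling. Of the erythroid list 0 of 5 measured members were higher and 4 lower, and both measured members of the miR-30 family were lower. The 4 include miR-486a-5p and miR-486b-5p, whose equal counts make them 1 signal. The let-7 family had 0 calls among 8 members, of which 7 had 0 counts with acetaminophen, so that their folds are bounds set by depth. The 4 erythroid folds are such bounds too, and the 1 measured member each of the hepatocyte-enriched, lymphoid, miR-17-92 and inflammation lists was not called.

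In all, 40 miRNAs were measured in that comparison, of which 11 were higher and 8 lower (57.89% of calls higher). Leaving out miR-122-5p and miR-30c-5p before scaling moved the median by -1.22 log2 and gave 11 higher and 15 lower (42.31% higher, against 61.11% of the calls on the same miRNAs). Both treated serum columns lacked detectable miR-30c-5p, miR-451a and miR-486a-5p, so the directions of these 3 against control do not depend on which of the conflicting serum labels is right. With the labels exchanged 15 of the 19 calls were shared, and miR-877-3p and miR-7058-3p, with 2 and 3 counts in the other treated column, would not reach the 10 counts needed. Against control, the G-CSF column had 16 higher and 8 lower of 45 measured, or 16 and 18 (47.06% higher, median moved by -1.22) without miR-122-5p and miR-30c-5p, with miR-466i-3p 405-fold higher (68.9 to 16358), miR-30c-5p at least 130-fold lower and miR-451a at least 5.74-fold lower.

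For serum exosomes, acetaminophen plus G-CSF against acetaminophen, the question is what G-CSF adds after acetaminophen. miR-5620-3p was 6.72-fold higher in the G-CSF column (31.5 against 3 counts, 2.1 to 34.3). miR-2137 (1 against 10 counts), miR-877-3p (2 against 18) and miR-7058-3p (3 against 17.5) were 15.9-fold (2.26 to 689), 14.3-fold (3.42 to 126.9) and 9.52-fold (2.78 to 50.5) lower. These were the 1 higher and 3 lower calls among 20 measured miRNAs, with 0 list members measured, and their directions turn if the titles rather than the treatment labels are right.

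For hepatocyte exosomes, acetaminophen against control, miR-2137 was 30.7-fold higher in the acetaminophen column (25 against 3 counts, 9.36 to 159), the 1 call among 5 measured miRNAs. Acetaminophen plus G-CSF against acetaminophen gave 0 calls among 1 measured miRNA. No list had a measured member in either comparison. The hairpin of miR-2137 lies at 72992079 to 72992144 of chromosome X (GRCm38) in an intron of Zfp185 and shares a 20-mer with 0 other annotated genes.

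Hepatocytes, acetaminophen against control, address the direct response of cultured cells. miR-21a-5p, a miRNA often raised in injury and growth, had 5536 counts in control and 58 with acetaminophen and was 18.1-fold lower (14.0 to 23.9) in the acetaminophen column. miR-21b was 23.8-fold lower (35 against 4389 counts, 17.1 to 34.3) and miR-31-5p 7.72-fold lower (8 against 325, 3.87 to 18). miR-19b-3p of the proliferation-linked miR-17-92 cluster was 5.99-fold lower (39.5 against 1262 counts, 4.38 to 8.43), and miR-103-3p and miR-107-3p, which share their reads, 8.97-fold lower (5 against 236.5, 3.79 to 27.9). miR-30c-5p was 9.86-fold higher (844.8 against 451.2 counts, 8.79 to 11.1), and the inflammation-linked miR-155-5p 121-fold higher (46 against 2 counts, 31.7 to 1030), while its hairpin, with more counts, was 20.5-fold higher (1572 against 293.3, 18.1 to 23.3). miR-2137 was 46.2-fold higher (237 against 27 counts, 31 to 71.6) and the endothelial miR-126a-5p 32.9-fold higher (25 against 4, 11.4 to 130). miR-122-5p was 1.29-fold higher (1.2 to 1.38; log2 0.36), under the 2-fold limit, and its log2 value ran from -0.24 to 0.74 over the alternatives tried, so that its direction turned.

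The other named miRNAs higher with acetaminophen in hepatocytes were miR-380-5p (15.8-fold), miR-6240 (11.2-fold), miR-489-3p (10.2-fold), miR-378b (7.81-fold), miR-130a-3p (6.44-fold) and miR-378a-3p (6.43-fold, with reads shared with miR-378c). Those lower were miR-503-5p (14.8-fold, 1 against 78 counts), miR-125b-5p (9.21-fold), let-7d-5p (5.7-fold) and miR-5099 (at least 5.95-fold). Of 100 measured miRNAs, 26 were higher and 27 lower (49.06% of calls higher). With DESeq2 size factors, which moved the median by 0.37 log2, the split was 29 to 20 (59.18%). With no filter before TMM, which moved it by -0.57, the split was 17 to 46 (26.98%). Shifts of this size cannot turn a call of at least 2-fold. The hairpin moved in the same direction for 50 of 53 called miRNAs, but its fold lay outside the interval of the mature fold for 26 of them, with a smaller difference in 21, so the sizes of the mature folds are less certain than their intervals.

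By list, the let-7 family had 0 higher and 6 lower of 9 measured members in the acetaminophen hepatocytes (median log2 fold -1.996), and miR-17-92 and paralogues 0 higher and 3 lower of 8 (-2.10, percentile 1.52). The miR-30 family had 4 higher of 5 (1.04, percentile 63.2), the hepatocyte-enriched list 3 higher of 5 (1.15, percentile 69.9), the miR-29 family 1 higher of 3 (0.61, percentile 62.3), and the p53 and hypoxia list 2 higher and 1 lower of 4 (1.13, percentile 71.2). The inflammation list had 1 higher and 1 lower of 4, with a median of -1.58 (percentile 12.4). Both endothelial members and the 1 measured lymphoid member (miR-155-5p) were higher, the 1 biliary and epithelial member (miR-31-5p) was lower, and neither of the measured erythroid members was called. The myeloid and the mesenchymal and stellate lists had 0 measured members in hepatocytes. Members of a family share divided reads (let-7a-5p and let-7c-5p had a ratio of 1 to 1.027 in 5 columns), so counts of let-7 members overstate their number, and no percentile is given for them. The percentiles of the miR-30 and miR-17-92 lists are affected as well.

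For hepatocytes, acetaminophen plus G-CSF against acetaminophen, all 3 members of the miR-29 family, which represses collagen genes, were higher in the G-CSF column: miR-29b-3p 2.56-fold (19.83 against 9.5 counts, 1.14 to 6.12), miR-29a-3p 2.3-fold (1.5 to 3.58) and miR-29c-3p 2.27-fold (1.49 to 3.52). miR-29a-3p and miR-29c-3p had similar counts (62.83 and 64.33 against 35 and 36.5), so they may not be separate. The percentile of this family, given below, would be affected as well. miR-101a-3p was 2.62-fold higher (80 against 39 counts, 1.77 to 3.95) and miR-30c-5p 2.17-fold higher (1437 against 844.8, 2 to 2.37). The hepatocyte-enriched miR-194-5p was 5.41-fold lower (24 against 166 counts, 3.51 to 8.69). miR-148a-3p, miR-152-3p and miR-148b-3p were 3.76-, 3.6- and 3.44-fold lower. They had 5.333 counts each in the G-CSF column against 24, 23 and 22, so they may be largely the same divided reads. miR-195a-5p, miR-16-5p, miR-489-3p and miR-126a-3p were 3.33-, 3.17-, 2.31- and 2.16-fold lower. miR-122-5p was 1.63-fold lower (443.3 against 920 counts, 1.45 to 1.82), under the 2-fold limit.

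Those calls were 5 higher and 8 lower among 47 measured miRNAs (38.46% higher), and the hairpin went the same way for 13 of 13. The hairpin fold lay outside the interval of the mature fold for 2 of them. Its log2 value was under the 2-fold limit for miR-29b-3p (0.65), miR-29a-3p (0.76), miR-29c-3p (0.76) and miR-101a-3p (0.99). The same held for miR-126a-3p (-0.38), miR-148a-3p (-0.92), miR-152-3p (-0.89) and miR-148b-3p (-0.90). For the remaining calls it was past that limit. The lower calls are not all separate, because miR-148a-3p, miR-152-3p and miR-148b-3p, and miR-16-5p and miR-195a-5p, had similar divided counts. DESeq2 size factors moved the median by 0.16 log2 and gave 5 higher and 7 lower. The median was 1.20 for the miR-29 family (percentile 98.6), 0.49 for the miR-30 family (1 higher of 5, percentile 88.7), -0.80 for the hepatocyte-enriched list (2 lower of 5, percentile 4.53) and -0.80 for the p53 and hypoxia list (1 lower of 3, percentile 4.69). All measured members of the p53 and hypoxia list here (miR-192-5p, miR-194-5p and miR-215-5p) belong to the hepatocyte-enriched list too. The medians of these lists are thus not separate results, and this overlap applies to the other comparisons as well. The erythroid and endothelial lists each had 1 lower member, and the measured lymphoid, miR-17-92 and inflammation members were not called. Against control, the G-CSF column of hepatocytes had 23 higher and 29 lower of 100 (44.23% of calls higher). With DESeq2 size factors, which moved the median by 0.53 log2, it had 27 higher and 18 lower (60%). Relative to control, miR-155-5p was 87.5-fold (26 against 2 counts, 21.9 to 760), miR-2137 50.3-fold and miR-30c-5p 21.4-fold higher (hairpins mir-155 16.6-fold, 14.5 to 19, and mir-30c-1 13.8-fold, 13.5 to 14.2), and miR-31-5p 24.2-fold, miR-34a-5p 15.6-fold and miR-21a-5p 12.9-fold lower.

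Liver, acetaminophen against control, addresses the response of the tissue. The red blood cell miRNA miR-451a had 87 counts in control and 1163 with acetaminophen and was 37.4-fold higher (30.1 to 47.1) in the acetaminophen column. Its cluster partners miR-144-3p (31 against 1 count, 14.5 to 3537) and miR-144-5p (27 against 1, 12.5 to 3094) were 86.8- and 75.6-fold higher, and miR-486a-5p 12.8-fold higher (32.5 against 7, 5.55 to 34.3). Hairpin mir-144, with more counts, was 19.4-fold higher (291.5 against 157.7, 15.9 to 23.7). miR-142a-3p, a miRNA of blood cells, was 9.89-fold higher (53 against 15 counts, 5.49 to 18.9), miR-29b-3p 8.91-fold (121.3 against 38.17, 6.15 to 13.2) and miR-2137 40.3-fold (72 against 5, 16.5 to 128). miR-122-5p was 1.9-fold higher (1.84 to 1.95), under the 2-fold limit, with a log2 value of 0.92 that ran from 0.54 to 1.10 over the alternatives tried. miR-103-3p and miR-107-3p were 6.02-fold lower (65 against 1095 counts, 4.68 to 7.85) and miR-99b-5p 6.07-fold lower (9 against 153, 3.12 to 13.5).

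The other named miRNAs higher in the acetaminophen liver column were miR-122-3p (11.7-fold) and miR-335-5p (6.4-fold). Those lower were miR-193a-5p (20.4-fold, 1 against 57 counts), miR-1195 (17.5-fold), miR-324-5p (14.7-fold), miR-29c-5p (7.86-fold), miR-192-3p (6.79-fold), miR-744-5p (6.79-fold) and miR-151-3p (6.43-fold). Of 161 measured miRNAs, 37 were higher and 44 lower (45.68% of calls higher). With column totals the median moved by -0.16 log2 and the split was 27 to 50 (35.06%). With no filter it moved by -0.26 and the split was 25 to 54 (31.65%). DESeq2 size factors (shift 0.17) gave 40 to 37 (51.95%) and leaving out miR-122-5p and miR-191-5p (shift 0.22) 41 to 33 (55.41%), so the majority depends on the scaling. Shifts of this size cannot turn a call of at least 2-fold. The hairpin moved in the same direction for 74 of 78 called miRNAs with a hairpin fold, and lay outside the interval of the mature fold for 26 (smaller in 24).

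By list, the erythroid miRNAs had 5 higher and 0 lower of 8 measured members in the acetaminophen liver (median log2 fold 3.68, percentile 100). These members are not all separate. The hairpins of miR-451a and miR-144 are neighbours in the same cluster, and miR-486a-5p and miR-486b-5p had equal counts in serum exosomes. The percentile treats them as separate and is affected by this. miR-17-92 and paralogues had 5 higher of 8 (1.21, percentile 93), the miR-29 family 2 of 3 (1.29, percentile 97), and both measured myeloid members were higher. The mesenchymal and stellate list had 3 higher and 1 lower of 7 (0.37, percentile 90.9), the endothelial list 1 higher of 2, and the inflammation list 1 higher of 7 (0.32, percentile 85.3). The let-7 family had 1 higher and 2 lower of 9 (-0.85), the p53 and hypoxia list 2 lower of 4 (-0.75, percentile 28.7), the lymphoid list 1 lower of 3 (-0.25, percentile 55.8), and the 1 biliary and epithelial member was lower. The hepatocyte-enriched list had 3 higher and 2 lower of 8 (0.33, percentile 88.3), a median that turns to -0.05 when miR-122-5p and miR-191-5p are left out. The miR-30 family had 0 calls among 5 (0.06, percentile 83.7), a median that turns to -0.10 with column totals.

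For liver, acetaminophen plus G-CSF against acetaminophen, miR-122-5p was 3.94-fold lower in the G-CSF column (5543 against 7902 counts, 3.8 to 4.07), with a log2 value of -1.98 that ran from -2.18 to -1.39 over the alternatives tried. miR-451a was 7.01-fold lower (458 against 1163 counts, 6.29 to 7.83), miR-144-3p 14.3-fold (6 against 31, 5.86 to 41.8), miR-486a-5p 8.03-fold (3.94 to 17.7) and miR-142a-3p 11.3-fold (13 against 53, 6.05 to 22.5). The hairpin of miR-142a was 3.01-fold lower (854.7 against 273.3 counts, 2.62 to 3.45), a smaller difference that lies outside the interval of the mature form. So does that of miR-144-3p, 4.355-fold lower (632.5 against 291.5 counts, 3.78 to 5.01). miR-31-5p was 4.57-fold higher (706 against 56 counts, 3.48 to 6.11), and the p53 target miR-34a-5p 4.15-fold higher (321 against 28, 2.82 to 6.35). let-7d-5p was 3.79-fold higher (900.4 against 85.6 counts, 3.04 to 4.79), miR-652-3p 4.84-fold (2.37 to 11.5) and miR-103-3p 3.39-fold (2.62 to 4.45). In every material the acetaminophen column is shared with the comparison against control, so that a chance value in it appears in both with opposite sign.

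Other named miRNAs higher with G-CSF in liver were miR-324-5p (12-fold, 33 against 1 count), miR-1195 (11.6-fold), miR-193a-5p (6.88-fold), miR-6240 (4.17-fold) and miR-668-3p (3.8-fold). Others lower were miR-144-5p (8.28-fold), miR-335-5p (7.36-fold), miR-126a-5p (5.59-fold), and miR-199a-3p with miR-199b-3p (4.73-fold). Of 163 measured miRNAs, 28 were higher and 21 lower (57.14% of calls higher). With column totals the median moved by 0.32 log2 and the split was 44 to 15 (74.58%). With DESeq2 size factors it moved by -0.20 and the split was 23 to 30 (43.4%). It was 43 to 15 (74.14%) with no filter and 22 to 29 (43.14%) without miR-122-5p and miR-191-5p. Shifts of this size cannot turn a call of at least 2-fold. The hairpin moved in the same direction for 43 of 43, and lay outside the interval of the mature fold for 19 (smaller in 18).

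Among lists in the G-CSF liver column, the let-7 family had 6 higher of 9 members (median 1.49) and the erythroid list 5 lower of 8 (-2.91, percentile 0). The linked erythroid members affect this percentile too. The hepatocyte-enriched list had 3 lower of 8 (-0.54, percentile 3.17), miR-17-92 and paralogues 1 higher and 2 lower of 8 (-0.94, percentile 4.99), and the miR-29 family 1 lower of 3 (-0.53, percentile 3.9). The mesenchymal and stellate list had 3 lower of 7, with a median of -0.05 that turns to 0.27 with column totals, and the p53 and hypoxia list 1 higher of 4, with a median of -0.02 that turns to 0.30. 1 myeloid and 1 endothelial member were lower, and the 1 biliary and epithelial member (miR-31-5p) was higher. The miR-30 family (0.31, percentile 46.5) and the lymphoid list (0.27, percentile 46.4) had 0 calls, and the inflammation list had 1 higher of 7 (0.27, percentile 52.1). The striated muscle, pancreas, neural and imprinted Dlk1-Dio3 lists had 0 measured members in any within-material comparison. Each list holds a selection, so this does not cover other miRNAs of the same tissues or cluster.

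Liver with acetaminophen plus G-CSF against control, which was not a planned comparison, does not use the acetaminophen column. In that comparison miR-6240 (92 against 1 count, 16.3 to 3724) and miR-2137 were 93.3- and 14.4-fold higher (hairpin mir-6240, with more counts, 7.22-fold, 2823 against 434.9, 6.52 to 8.001), miR-451a 5.34-fold (458 against 87 counts, 4.24 to 6.79), miR-223-3p of myeloid cells 4.96-fold (141.8 against 29, 3.31 to 7.68) and miR-29b-3p 4.08-fold. miR-378a-3p was 3.36-fold lower (2.82 to 4.03) and miR-122-5p 2.07-fold lower (2.01 to 2.14). Hairpin mir-122 was 1.81-fold lower (62321 against 125059.3 counts, 1.79 to 1.82), under the 2-fold limit and outside the interval of the mature form. Of 172 measured miRNAs, 27 were higher and 22 lower (55.1% of calls higher). With column totals, which moved the median by 0.16 log2, the split was 29 to 15 (65.91%).

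**Figure D2:**
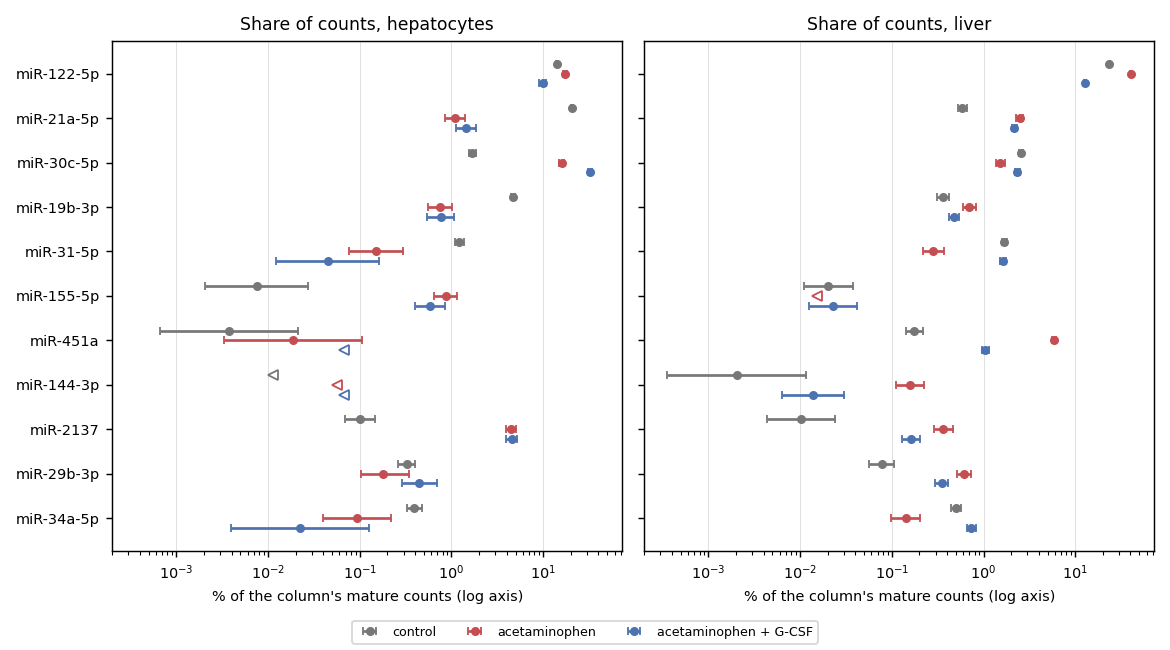
Percentage of mature counts (log axis) on 11 miRNAs in the 3 columns of hepatocytes (left) and of liver (right), with 95% Wilson intervals as bars and, for a count of 0, the share that 3 counts would give as an open triangle. miR-21a-5p takes 20.7% in control hepatocytes and 1.088% with acetaminophen, and miR-451a stands at 0.1764%, 5.905% and 1.048% in the 3 liver columns.

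**Figure D3:**
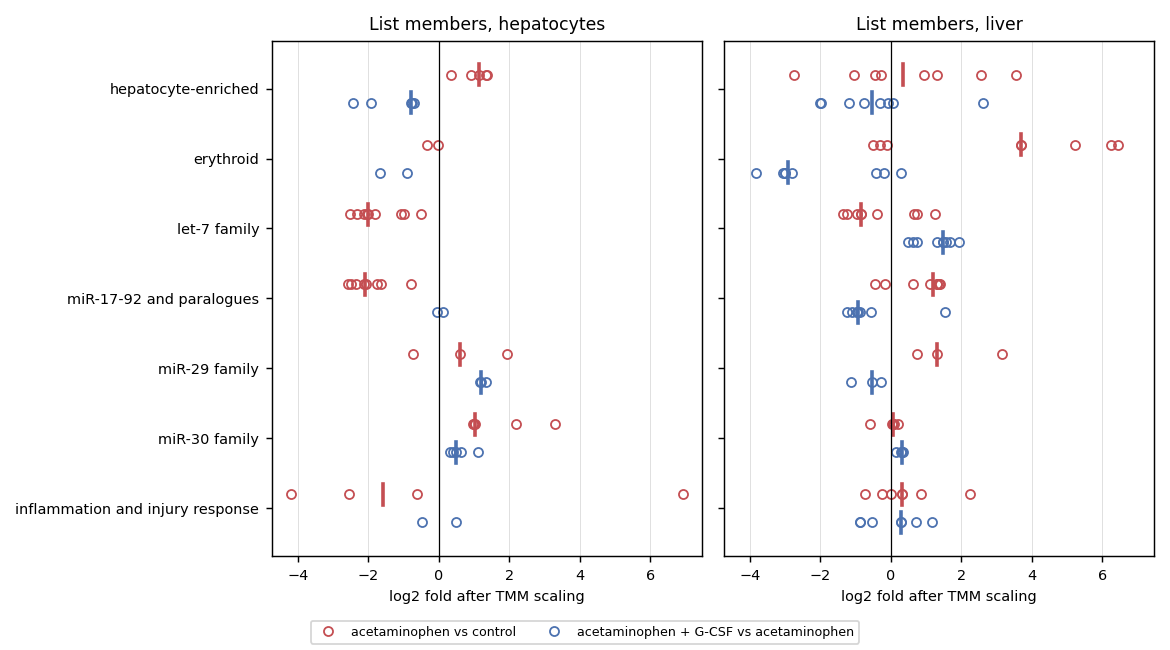
Log2 folds of the measured members of 7 lists (circles) and their median where at least 3 were measured (bars) in hepatocytes (left) and liver (right) after TMM scaling. The let-7 family has medians of -1.996 in acetaminophen-treated hepatocytes and 1.49 in liver with G-CSF added, and the liver miR-30 family (acetaminophen) and hepatocyte-enriched list (acetaminophen) turn direction under another scaling.

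Hepatocyte exosomes were compared with hepatocytes over the 3 treatments to ask which cellular miRNAs the vesicles carried. The fit called miR-192-5p lower in exosomes with a log2 fold of -12.68 (SE 3.31, edgeR adjusted p 0.00659), miR-21a-5p with -12.66 (SE 3.98, 0.00937), miR-30b-5p with -13.77 (SE 4.6, 0.0142) and miR-30c-5p with -15.56 (SE 6.62, 0.0424). These folds depend on the TMM factors and on the prior count, since the exosome counts round to 0, and they are no bounds. As shares of the column totals, with exact intervals, a lower level in exosomes was detectable in no treatment for 36 of the 51 miRNAs called lower, and in 3 of 3 only for miR-30c-5p (at least 1.88-, 4.81- and 5.06-fold in the order control, acetaminophen, G-CSF) and miR-30b-5p. It was detectable in 2 of 3, not with G-CSF, for miR-192-5p and miR-215-5p, and in 1 of 3 for 11 miRNAs, among them, in control alone, miR-21a-5p (at least 23.1-fold), miR-21b (at least 18.3-fold), miR-191-5p and miR-16-5p. For miR-380-5p, miR-378a-3p, miR-378c and miR-130a-3p, which the fit also called lower, it was not detectable at this depth in any treatment. miR-669c-3p was called higher with 7.996 (SE 3.44, 0.0426) and miR-466i-3p with 7.83 (SE 3.39, 0.0438), each in the same direction in 3 of 3 treatments, from 9, 2 and 3 and from 8, 4 and 2 counts in exosomes. Of 87 miRNAs tested, 2 were called higher and 51 lower with TMM. With column totals, which moved the median log2 fold by 0.23 toward zero, 13 were called higher and 0 lower, and 2 miRNAs were called under both. The stricter filter and the fit of only the 6 columns compared each gave 0 calls, so that none of the 53, these 2 included, held under every alternative.

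Serum exosomes against liver gave 0 calls with edgeR (47 of 87 at an unadjusted p under 0.05, smallest adjusted p 0.0622), 18 higher and 39 lower with column totals, and 8 higher and 12 lower with DESeq2. Serum against hepatocyte exosomes gave 0 calls with edgeR (15 at an unadjusted p under 0.05, smallest adjusted p 0.255) and 8 higher with DESeq2. Hepatocytes against liver gave 0 calls with edgeR (7 at an unadjusted p under 0.05, smallest adjusted p 0.164). miR-122-5p had a fitted log2 fold of -7.65 in serum exosomes against liver, -9.07 in hepatocyte exosomes against hepatocytes and -0.80 in hepatocytes against liver. Over the alternatives tried these ran from -17.45 to -4.77, from -13.69 to -1.13 and from -6.98 to 0.32. Relative to column totals, TMM moved the median log2 fold by -0.25 for serum exosomes against liver and by -0.67 for serum against hepatocyte exosomes. The common dispersion was 1.92 and the TMM factors ran from 0.123 to 53.3.

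Across all 4 materials, acetaminophen with or without G-CSF against control gave 0 calls with edgeR among 87 miRNAs (5 at an unadjusted p under 0.05, smallest adjusted p 0.568), and DESeq2 called 5 lower. miR-122-5p had a log2 fold of -2.13 there, where TMM moved the median of all miRNAs by -1.67 relative to column totals. G-CSF with acetaminophen against acetaminophen gave 0 calls (0 at an unadjusted p under 0.05, smallest adjusted p 0.986). The common dispersion of these 12 columns was 1.92. At a simulated dispersion of 1, the fit of 12 columns for acetaminophen against control called 0 of 18 tested 16-fold changes. The lack of calls therefore does not show that the treatments had no effect shared by the materials. In a fit of hepatocytes and liver alone, chosen after seeing the data, miR-6240 rose by a log2 fold of 4.29 (SE 1.08, adjusted p 0.0106) and miR-2137 by 5.16 (SE 1.45, adjusted p 0.0243) among 109 miRNAs tested (13 at an unadjusted p under 0.05). The hairpin of miR-6240 shares a 20-mer with 9 other annotated genes, so the origin of its reads is not certain. Its hairpin folds against control were all smaller than the fitted one. With acetaminophen and with G-CSF added they were 8.55 and 6.27 in hepatocytes and 3.735 and 7.22 in liver. Of 36 camera tests over 6 lists and 6 comparisons, 0 had an adjusted p under 0.05 with TMM (smallest 0.0603, and 0.817 with an estimated correlation). With column totals 1 list, the let-7 family with 8 members tested, was lower in hepatocytes than in liver (median log2 fold -3.43, adjusted p 0.0156), a call that did not hold with an estimated correlation (0.892).

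Positions of the hairpins in GRCm38 were as follows. mir-122 lies at 65248861 to 65248926 of chromosome 18 in an exon of a long noncoding RNA, mir-21a at 86584067 to 86584158 of chromosome 11 in an exon of Vmp1, and mir-155 at 84714140 to 84714204 of chromosome 16 in an exon of Mir155hg. mir-451a lies at 78073170 to 78073241 of chromosome 11, with mir-144 at 78073005 to 78073070, and mir-31 at 88910557 to 88910662 of chromosome 4. mir-30c-1 lies at 120769534 to 120769622 of chromosome 4 in an intron of Nfyc and mir-30c-2 at 23291701 to 23291784 of chromosome 1.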

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

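Every test in this part was chosen after the result it examines had been seen.

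7 miRNAs were called in opposite directions in hepatocytes and in liver, for acetaminophen with and without G-CSF against control, and were singled out for that. For miR-21a-5p the log2 fold of acetaminophen against control was 6.43 higher in liver, where it was 4.75-fold higher than in control (492.2 against 289.7 counts, 4.1 to 5.51), than in hepatocytes, where it was 18.1-fold lower. The difference was 6.76 for miR-21b and 3.36 for miR-98-5p of the let-7 family, which was 2.36-fold higher in liver (1.69 to 3.28). In the other direction it was -4.85 for miR-378a-3p and -4.85 for miR-378c, whose counts are identical, -5.21 for miR-378b and -6.40 for miR-380-5p. miR-378a-3p, encoded in a gene of energy metabolism, was 6.43-fold higher in acetaminophen-treated hepatocytes and 4.48-fold lower in the acetaminophen liver column (44.33 against 552.5 counts, 3.29 to 6.24). miR-380-5p had 0 counts against 45 in liver, at least 5.36-fold lower.

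The difference between materials in the response to acetaminophen, with or without G-CSF, was then tested with edgeR. The test takes both treated columns of a material as replicates and assumes that its lone control column varies like them. On the 6 columns of hepatocytes and liver (2 residual degrees of freedom), 13 of 109 miRNAs differed (4 higher and 9 lower in liver), and 7 of them with column totals. Among them were 6 of the 7 above, with log2 differences of 5.90 for miR-21a-5p (SE 1.28, adjusted p 0.003), 6.53 for miR-21b (SE 1.24, 0.00156), -4.59 for miR-378a-3p and miR-378c (SE 1.07, 0.0034), -4.82 for miR-378b (SE 1.07, 0.00317) and -6.65 for miR-380-5p (SE 1.37, 0.00225). miR-98-5p did not pass (3.81, SE 1.37, 0.066). In the fit of 12 columns (4 residual degrees of freedom) serum exosomes and liver differed for 47 of 87 miRNAs, all lower in serum. With column totals 9 were higher and 5 lower, and only these 5 were called under both, so the direction of the whole set depends on the scaling, and most calls rest on counts of 0 in shallow columns. Hepatocyte exosomes and hepatocytes differed for 0 of 87.

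6 hairpins whose mature forms had 0 counts in all 12 columns stood out because their hairpin counts, which enter no comparison of mature miRNAs, exceeded the control column with acetaminophen and with G-CSF added, with at least 500 counts in each. In hepatocytes with acetaminophen, mir-3066 (17355392 to 17355474 of chromosome 12 in an intron of Nol10) was 2664-fold higher (2096 against 3 counts, 910 to 12928). mir-6949, in an intron of the mast cell protease gene Mcpt8, was 56.9-fold higher (1104 against 74 counts, 44.9 to 73), mir-6481 17.5-fold (10681 against 2332, 16.7 to 18.3) and mir-6236 8.38-fold (7.61 to 9.24). With G-CSF added the folds against control were 2275, 81.2, 13.6 and 8.54. The hairpin of mir-6236 shares a 20-mer with 17 other annotated genes, so the origin of its reads is not certain. For mir-3066, mir-6949 and mir-6481 these numbers were 0, 0 and 1. In liver, mir-451b, which lies on the strand opposite mir-451a, was 31.6-fold higher (5254 against 1744 counts, 29.9 to 33.4), and mir-3965 3.24-fold higher (3.08 to 3.42). Both follow another hairpin: the ratio of mir-451b to mir-451a was 0.979 and that of mir-3965 to mir-21a 0.958 in the acetaminophen liver column, so neither was a separate signal. None of these differences was tested.

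The lower miR-21a-5p and miR-19 of acetaminophen-treated hepatocytes were weighed against 5 technical explanations. A few miRNAs taking most of the counts is argued against, since over 5 scalings the smallest decrease was 8.91-fold for miR-21a-5p and 3.82-fold for miR-19b-3p. Fewer endothelial or mesenchymal cells in the treated cultures are argued against as well. Endothelial miRNAs (both arms of miR-126a) were 5.56-fold (94 against 89 counts, 4.12 to 7.51) and with G-CSF added 4.16-fold higher (55 counts, 2.92 to 5.88). Mesenchymal hairpins were 7.36- and 3.8-fold higher (224 and 82 against 116 counts, 5.86 to 9.29 and 2.83 to 5.09). Myeloid hairpins stood at 1.42 (28 against 75 counts, 0.888 to 2.22) and 1.51 times control (21 counts, 0.882 to 2.47). Their lowest limit over 4 scalings, 0.532, lies just above a 2-fold loss and covers counting error only. Variation between cultures is not covered with 1 column each, so fewer myeloid cells are not decided. An unusual control culture stays open: with 1 control column, whose miR-21a-5p share was 35.2 times that of control liver (31.3 to 39.8), it cannot be told apart from a treatment effect. A loss of growth-linked miRNAs in damaged cultures may also explain the pattern, as a hypothesis that these columns cannot decide.

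The higher erythroid miRNAs of the acetaminophen liver column were weighed in the same way. A few miRNAs taking most of the counts is argued against by the smallest increase of miR-451a over the scalings, 31.2-fold. Mature counts were 17.69% of hairpin counts in that column, against 2.965% to 3.988% in the other 6 deep columns, a difference whose origin was not tested, but a different selection of mature reads as the cause is argued against by hairpin mir-451a, 31.7-fold higher (5369 against 1773 counts, 30.1 to 33.5). Blood left in the tissue could be the source and was not decided: the ratio of miR-486a-5p to miR-451a was 0.0275 (0.0187 to 0.0391), against 0.0805 in control liver (0.0314 to 0.173) and 1.41 in control serum exosomes (1.15 to 1.74), while miR-16-5p was 1.09-fold lower than in control (0.949 to 1.25). Bleeding into injured tissue, a biological explanation that the treatment offers, cannot be told apart from blood retained at collection, since no sample of whole blood was used here.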

How the results depend on the processing

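Hairpin counts outside the comparisons of treatments across materials, and the fit of hepatocytes and liver alone, were alternatives chosen after seeing the data; the others were planned. Counts of calls stayed within 1.5 times the main count in 81 of 108 alternatives and moved in 27. The log2 fold of miR-122-5p was the same in 51 of 81, past the threshold in 6, moved in 11 and reversed in 13. Some of the unchanged values could not have differed. Within materials the stricter filter kept the same mature miRNAs, and in both exosome materials column totals were already the main scaling. The unchanged counts therefore overstate how stable the results were. Where a value moved or reversed, the cause was not tested, except that hairpin counts are deeper and leaving out columns leaves fewer samples. Within materials, no call turned direction under another scaling, which could hardly have come out otherwise. Another scaling moves every fold of a comparison by the same amount. In hepatocytes and liver the largest shift was -0.57 log2, less than the 2-fold limit of a call. In serum exosomes the shift of -1.22 moved the lower calls further from equality, and the higher calls were far larger. Hairpin counts gave 114 calls for serum exosomes and 190 for hepatocytes (acetaminophen against control), 157 for liver, 2 for hepatocyte exosomes and 173 for hepatocyte exosomes against hepatocytes, and for G-CSF added to acetaminophen 53 in hepatocytes, 119 in liver and 2 in hepatocyte exosomes. In hepatocyte exosomes the acetaminophen comparison had 0 calls without miR-122-5p and miR-2137 (by construction, since miR-2137 is its only call), and the G-CSF comparison 1 with no filter. With column totals, hepatocyte exosomes against hepatocytes had 13 calls in place of 53, and serum exosomes against liver 57 in place of 0. DESeq2 gave 5 calls for acetaminophen across materials, 20 for serum exosomes against liver and 8 for serum against hepatocyte exosomes. For hepatocyte exosomes against hepatocytes, no filter gave 34 calls (27 of them among the 53), the stricter filter 0 and only the 6 columns compared 0. Only the 6 columns gave 13 calls for hepatocytes against liver.

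Leaving out each treatment in turn gave 0 to 13 calls for hepatocyte exosomes against hepatocytes, 0 to 63 for serum exosomes against liver, 0 to 1 for serum against hepatocyte exosomes and 0 to 53 for hepatocytes against liver, the highest each time without control. Without any 1 of the treatments, the 51 miRNAs lower in hepatocyte exosomes were no longer called. Leaving out each material gave 0 to 4 calls for acetaminophen against control, the 4 without serum exosomes, and hepatocytes and liver alone gave 2. For miR-122-5p, G-CSF added to acetaminophen across materials had a log2 fold of 0.03, which became -0.36 with column totals, -0.35 with DESeq2, -0.74 with no filter, -0.43 with the stricter filter, -0.53 with hairpin counts and -1.45 with hepatocytes and liver alone, and ran from -0.94 to 1.48 leaving out each material. Acetaminophen against control went from -2.13 to 0.0281 with hepatocytes and liver alone, its highest value, and was lowest at -6.18 without liver. Serum against hepatocyte exosomes went from 2.22 to -1.88 with column totals ran from -9.34 (without control) to 4.55 leaving out each treatment, and was highest at 6.15 with hairpin counts. Hepatocytes against liver went from -0.80 to 0.0439 with only the 6 columns and ran from -6.98 (without control) to 0.32 (without acetaminophen). Exchanging the serum labels gave 24 calls in place of 19, of which 15 were shared.

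Other divisions of the columns gave these counts of calls. Where the real division gave 0 calls, every division gives as many by construction, so these counts say nothing about chance: 100 of 100 for acetaminophen across materials and 35 of 35 for G-CSF. Their highest others, 48 and 38, are far above the real counts, and the reason was not tested. For hepatocyte exosomes against hepatocytes the real value was 53 (1 of 10 divisions) and the highest other 0, for serum exosomes against liver 0 and 0 (10 of 10), for serum against hepatocyte exosomes 0 and 3 (10 of 10), and for hepatocytes against liver 0 and 2 (10 of 10), divisions too few for a share under 0.05.

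Not run, because both instruments had been combined, were the fits of 24 libraries, the instrument block, each instrument alone, leaving out each library and the rule on both instruments; differences between materials were tested on the combined columns instead. The 6 columns of serum and hepatocyte exosomes left too few miRNAs for a value, and DESeq2 size factors could not be estimated within either exosome material. No paired analysis was possible because each condition had 1 column and nothing in the labels paired animals or cultures. Depth limits the exosomes most: in the 5 columns with fewer than 1000 counts a count of 0 allows 0.4335% to 6.383%.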

Other observations

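The tests and the miRNAs named in this part were chosen after the results had been seen, except the search for repeat-like hairpins, whose bounds were written beforehand.

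The arms of the miR-122 hairpin differed in direction in the G-CSF column of liver. The minor arm miR-122-3p had 6, 25 and 30.5 counts in the control, acetaminophen and G-CSF columns, against 11657.2, 7902 and 5543 for the major arm. With G-CSF added, miR-122-3p was 5.07-fold higher than in control (2.08 to 14.9) while miR-122-5p was 2.07-fold lower and hairpin mir-122 1.81-fold lower. The reverse held for miR-29c in the acetaminophen column, where the major arm miR-29c-3p was 2.45-fold higher (301.8 against 344.7 counts, 2.09 to 2.87) and miR-29c-5p 7.86-fold lower (1 against 22.5 counts, 1.27 to 324).

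Myeloid miR-223-3p was 4.83-fold higher than in control in the acetaminophen liver column (50.5 against 29 counts, 2.99 to 7.91) and 4.96-fold higher with G-CSF added. miR-142a-3p was 9.89-fold higher with acetaminophen and had too few counts to tell with G-CSF added (13 against 15, 0.385 to 1.98). Its hairpin, with more counts, was higher in both (5.55-fold, 4.77 to 6.43, and 1.84-fold, 854.7 against 515.7 counts, 1.65 to 2.06). The lymphocyte miRNA miR-150-5p did not differ from control beyond counting error in either column (1.23-fold, 0.665 to 2.19, and 1.14-fold, 0.73 to 1.78). The pancreatic miRNAs miR-216a-5p, miR-216b-5p, miR-217-5p and miR-375-3p had 1, 1, 5 and 3 counts in the acetaminophen liver column and 0 in the other liver columns, which allow up to 0.006081% (control) and 0.006865% (G-CSF).

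In the 5 exosome columns with fewer than 1000 mature counts few counts fell on the listed miRNAs. Low depth alone is argued against, since the highest upper limit of their shares was 11.1%, under the 61.64% that was the lowest share of the other 7 columns. Acetaminophen as the whole cause is argued against too, since the untreated hepatocyte exosomes reached an upper limit of 5.41%. Reads from repeats or other transcripts may be a source: repeat-like hairpins took 42.82%, 42.73%, 35.68%, 20.27% (14.7 to 26.91) and 26.94% of the hairpin counts of these columns and at most 0.301% in the other 7, but only 4 of the 5 lay above the bound of 25% set beforehand, so the test did not decide. Vesicles that truly hold few miRNAs, or libraries with little RNA, stay open and untested.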
